A study of Arabidopsis thaliana with 8 samples.

How the data were processed

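The series holds 8 single-colour arrays of Arabidopsis thaliana seedlings, 4 of the bil1-1D (bzr1-1D) mutant given brassinolide and 4 of wild type given DMSO, all after 14 days with 1 µM brassinazole. Per the labels' protocols, plants grew on agar medium at 22 °C with 16 hours of light and 8 hours of dark, the treatment with 1 µM brassinolide or DMSO lasted 3 hours, RNA was isolated with a QIAGEN RNeasy kit, and 200 ng of total RNA was labelled with Cy3 by Agilent's low-input kit. Groups were taken from the labels.

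Each scanner file holds spot intensities on a linear scale, deposited by the authors as Agilent Feature Extraction wrote them. The processed signal is the background-subtracted and detrended intensity of a spot, with no normalization between arrays, per the file headers. The file headers name Feature Extraction 11.5.1.1 and array design 021169, while the submitters' processing notes name version 9.1.3.1. The version that made the deposited values could not be settled beyond the header. The authors' value table holds 1 value per probe and array. It appears to be on a natural log scale, since its slope against the natural log of the processed signal was 0.986 to 1.02 over the middle of the range, but the log base is an inference from the deposited values. Its columns held identical sets of values with a median of -0.970 each, so the table was quantile normalized; the centring and the target distribution stay unknown, and the step is not given in the sources used here. It was used as an alternative only.

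Each array had 43803 spots that are not controls, for 43603 probes. Over all arrays 93 outlier spots were left out and 0 were saturated. Probes were matched to loci by looking up their accessions in the RefSeq gene table, where 36163 matched 1 Arabidopsis locus and 7440 matched none. Symbols came from the gene lists below for their members and from the RefSeq gene table for other loci. The probes covered 26716 loci, 7320 of them by over 1 probe.

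Spots of a probe were averaged, the processed signal was divided by the array's 75th percentile over probes that are not controls, values under 0.001 of the percentile were set to it, and log2 was taken. A probe was tested if it was well above background on all arrays of at least 1 group, and a gene was represented by its tested probe with the highest mean over the 8 arrays. Of the genes called, 555 had a further probe past the threshold in the opposite direction, 9 of them among the 2-fold changes and none among the genes named here. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over 22101 genes and a threshold of 0.05. Gene lists were compared with the other genes by camera with a preset inter-gene correlation of 0.01, adjusted over 29 lists of at least 3 tested genes; they held 468 genes, of which 458 were tested. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

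A gene not well above background on any array of a group has only a bound there. It was computed as the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, on normalized log2 values. With an n of 4 arrays per group, the exact two-sided permutation test cannot give a p below 0.0286.

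The tests, gene lists and the rule for named genes were set before the data were examined. The rule took 19 genes named in advance. It added the 6 largest rises and 6 largest falls among called genes well above background on all 8 arrays whose groups did not overlap. Its 2 highest and 2 lowest bounds among genes detected in 1 group only were taken as the 2 highest of each group. For each list with at least 3 members past the threshold, it added the 2 largest changes in the direction most of these took. The largest change in the other direction was added too. It named 109 genes.

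The alternatives set in advance were quantile and median scaling, normexp background correction with an offset of 50, the authors' value table, no filter and a filter on all 8 arrays, the mean of a gene's probes, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array, another detection flag, the brightest probe alone for detection, an estimated correlation and fry. Normexp was planned on the mean spot signal and ran on the median spot signal and local background, since the files used here hold no mean signal. Blocks for slide and scan could not be fitted, since each slide and scan holds 1 group. Spike-in scaling, cyclic loess, normexp with 153 negative-control spots and the fit without the 3 arrays that the scanner software marked for evaluation were chosen after seeing the data.

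The fit was tested on simulated data made from the spread of the arrays. Among 22082 genes, 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. The fit recovered 50.7%, 82.1% and 97.0% of these and called 4 unchanged genes. In the real data 55.9% of the genes were called, which makes the Benjamini-Hochberg cutoff on p less strict. These gene rates therefore need not hold for the real fit. With lists shifted by 0.5, camera called 100 of 100 shifted and 3 of 480 unshifted lists. The simulated noise was drawn independently for each gene, so these list rates hold only without correlation between genes. In the real lists the estimated correlation reached 0.68.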

Results

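Transcript levels were measured in Arabidopsis thaliana seedlings of the Col-0 background on 8 single-colour Agilent arrays. All seedlings had grown for 14 days with 1 µM brassinazole, an inhibitor of brassinosteroid synthesis that lowers the plant's own hormone. In 1 group, 4 samples of the dominant mutant bil1-1D (also named bzr1-1D), which carries an altered form of the brassinosteroid-responsive transcription factor BZR1, then received 1 µM brassinolide, the most active brassinosteroid, for 3 hours. In the other group, 4 wild-type samples received the solvent DMSO for 3 hours. The series asks which genes respond to brassinosteroid, and its design implies 1 comparison, the brassinolide-treated mutant against the solvent-treated wild type. Genotype and treatment changed together, so no value below separates them. The 4 arrays of the mutant lay on 1 slide and the 4 of the wild type on another, each scanned on its own, so slide and group cannot be told apart. Nothing in the labels says that the samples of a group came from separate cultures, and the p-values therefore measure only the spread between these samples, which may be technical.

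The mutant slide was dimmer. The 75th percentile of the processed signal lay between 3011 and 3807 on the mutant arrays and between 4613 and 6128 on the wild-type arrays, and 74.5% to 75.8% of the spots were well above background on the former against 79.5% to 80.6% on the latter. No spot was saturated. Array number limits the precision of every value. After scaling each array to its 75th percentile, Pearson correlations across genes were 0.990 to 0.996 within groups and 0.967 to 0.976 between them, and the first principal component, with 74.0% of the variance, separated the groups. Levels are given as normalized log2 signal, where 0 is the array's 75th percentile, as mean ± SD over 4 arrays. Changes are log2 fold changes of the mutant with brassinolide over the wild type with DMSO ± SE, with limma's Benjamini-Hochberg adjusted p.

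Genes that make brassinosteroids were lower in the brassinolide-treated mutant, and small auxin-up RNA (SAUR) genes, which act in cell expansion, were higher. DWF4, the C-22 hydroxylase often described as rate-limiting for brassinosteroid synthesis, was 66.3-fold lower (-4.77 ± 0.14 against 1.28 ± 0.18; change -6.05 ± 0.11, adjusted p = 6.5e-08). SAUR21 (AT5G18030) was 26.1-fold higher (0.10 ± 0.36 against -4.61 ± 0.87; change 4.71 ± 0.41, adjusted p = 6.0e-05). BAS1, a cytochrome P450 that inactivates brassinosteroids, was 8.08-fold higher, and the receptor gene BRI1 was 3.52-fold lower. Several glucosinolate and light-response genes were lower as well.

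Of 22101 genes tested, 12355 (55.9%) passed the threshold, of which 6679 rose and 5676 fell. Most of these changes were small, with 8076 of them under 1.5-fold, and 1790 genes (8.10%) changed at least 2-fold, 680 upward and 1110 downward. Among genes well above background on all 8 arrays, 638 rose and 788 fell as much, so much of the excess of falls rests on genes not well above background on some array. At least 4-fold, 101 rose and 248 fell. The groups did not overlap for 11536 genes (52.2%), where chance gives 2.86%. Scaling to the spike-in RNAs instead, an alternative chosen after seeing the data, moved the median of all genes by -0.12 and left 1410 rises and 2989 falls past the threshold, while 530 genes rose and 1368 fell at least 2-fold. Of the 109 genes named here, 20 lost their call under that scaling and none turned direction: CACS, RBCS2B, BIN2, BPG2, MYB83, EPF1, TUB2, ACT8, ELF4, TMM, XTH22, BZR1, PXY, JAZ12, PRR3, ARR5, TT8, CYCD3;1, CYCD6;1 and FLC. The spike-ins varied between arrays of the same group. After 75th percentile scaling, the SE of a spike-in probe's difference between the groups was 0.11 to 0.24. Scaling to the spike-ins adds such spread to every gene, so a lost call need not come from the shift of -0.12. With the normexp background correction, 3973 genes rose and 5080 fell past the threshold. At least 2-fold, 231 rose and 1902 fell, and 272 of the 680 2-fold rises turned sign. The background it fitted was far below 0 on 3 wild-type arrays, so losses and turns under it alone do not show that a call depends on background. With normexp on the negative-control spots, also chosen after seeing the data, 1164 genes changed at least 2-fold, 554 upward and 610 downward. Of the 1110 falls, 142 turned sign. The fixed offset of this form is a larger share of the dimmer slide's signal and lifts dim genes there. These turns therefore do not show that the falls came from background. Without the 3 arrays that the scanner software marked for evaluation, again chosen after seeing the data, RD29B, AOC3, RBCS2B, BPG2, MYB83, XTH22, FLC, PRE1 and TIP2;3 lost their calls, and counts in the lists below moved: 8 bHLH factors, 8 gibberellin genes, 5 clock genes and 5 brassinosteroid inactivation genes rose, and 7 glucosinolate genes and 1 jasmonate gene fell.

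**Figure D1:**
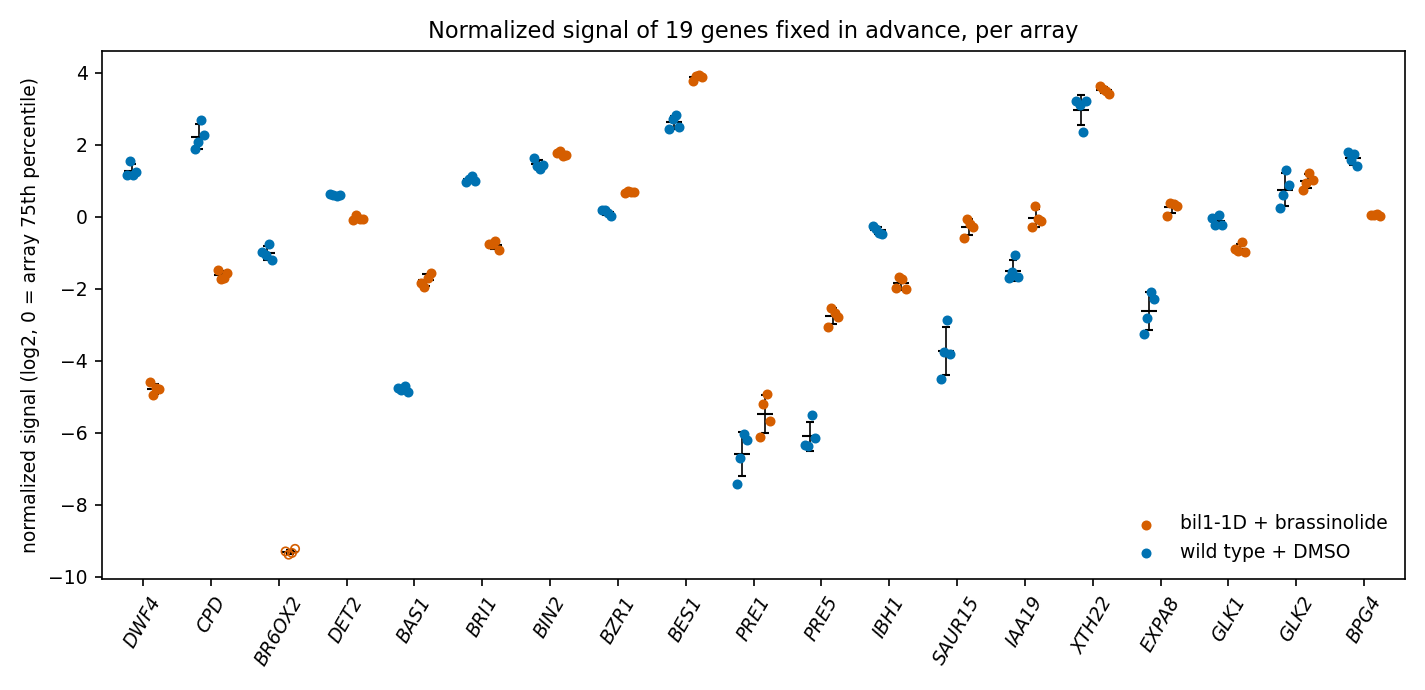
Normalized log2 signal (0 is the array's 75th percentile) of the 19 genes fixed in advance, with 1 point per array, bars at the mean ± SD of 4 arrays, orange for bil1-1D with brassinolide and blue for wild type with DMSO; hollow points belong to a group in which the gene was not well above background on all arrays. DWF4 lay at -4.77 ± 0.14 in the mutant and 1.28 ± 0.18 in the wild type, whereas the points of GLK2 overlap.

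All 10 tested brassinosteroid biosynthesis genes fell, 7 of them at least 2-fold, with a list median of -2.72 (-2.34 with BR6OX1 and BR6OX2, which were not well above background on any mutant array, at their bounds). BR6OX2, which catalyses the last step to brassinolide, was well above background on all 4 wild-type arrays (-0.99 ± 0.19) and on none of the mutant arrays (-9.31 ± 0.07), and was at least 90.5-fold lower (adjusted p = 6.8e-09). The P450 genes CYP90D1 (-4.84 ± 0.11, adjusted p = 1.3e-07) and CPD (-3.84 ± 0.16, adjusted p = 2.1e-06) fell strongly, and the 5-alpha-reductase gene DET2 (-0.65 ± 0.05, adjusted p = 2.1e-05) by the least of the named members. The list was shifted downward as a whole (camera, adjusted p = 2.4e-08; adjusted p = 0.0537 with an estimated correlation). Of 7 brassinosteroid inactivation genes, 3 rose, none fell and 4 did not pass the test. BAS1 (3.01 ± 0.09, adjusted p = 3.9e-07) and the reductase gene BEN1 (1.01 ± 0.10, adjusted p = 9.6e-05) led them, and with normexp 1 gene rose and the call of BAS1 was lost (1.17, adjusted p = 0.0856). The list was not called (median 0.62, adjusted p = 0.197).

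Among 15 brassinosteroid signalling genes, 5 rose, 8 fell and 2 did not pass, without a call for the list (median -0.35, adjusted p = 0.197). The receptor genes BRI1 (-1.82 ± 0.07) and BRL3 (-2.24 ± 0.08) fell, as did BEH2 (-3.76 ± 0.05, adjusted p = 6.8e-09), a homologue of BZR1. BES1 (1.26 ± 0.09, adjusted p = 2.5e-05), the closest relative of BZR1, rose, and BZR1 (0.57 ± 0.05) and the kinase gene BIN2 (0.30 ± 0.07) rose by smaller amounts. The probe for BZR1 reads its transcript and does not test the mutation. With spike-in scaling, the calls of BZR1 (0.45, adjusted p = 0.151) and BIN2 (0.17, adjusted p = 0.668) were lost. Of 5 genes named from brassinazole screens, 3 fell, 1 rose and 1 did not pass (median -0.86, adjusted p = 0.112). BIL7 (-3.27 ± 0.15, adjusted p = 3.2e-06) and BPG4 (-1.58 ± 0.09, adjusted p = 7.2e-06) fell. BPG2 (0.34 ± 0.12, adjusted p = 0.0395), a chloroplast protein gene, rose, but that call was lost on leaving out any of 7 arrays (adjusted p up to 0.0932).

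**Figure D2:**
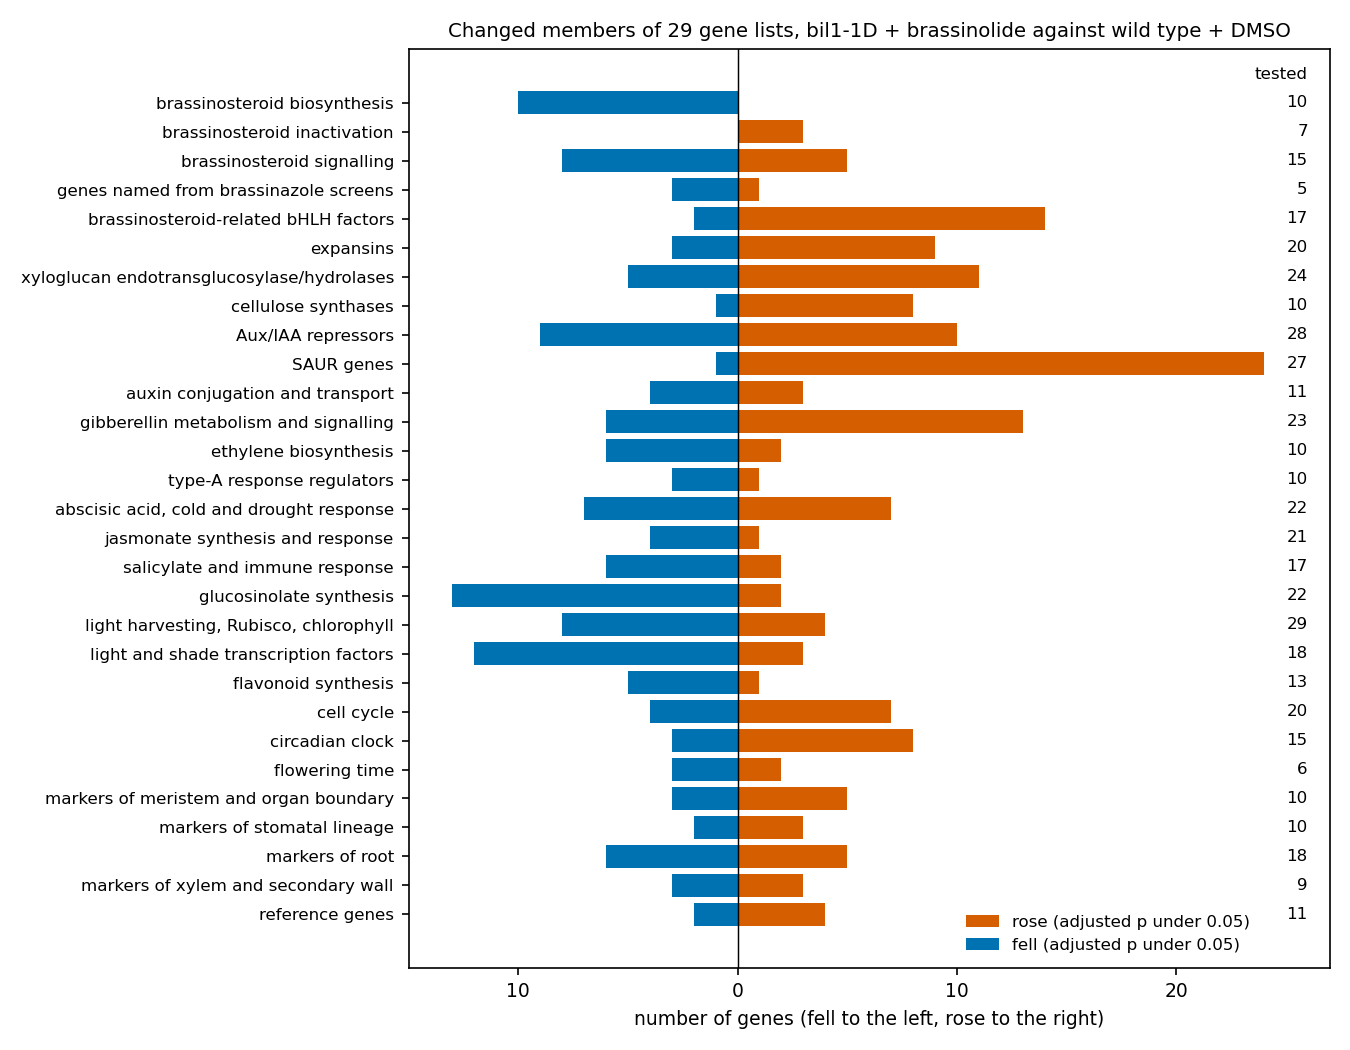
Number of members that rose (orange, to the right) and fell (blue, to the left) at an adjusted p under 0.05 in each of the 29 gene lists, with the number tested beside each bar. All 10 brassinosteroid biosynthesis genes fell, and 24 of 27 SAUR genes rose. These counts were 10 and 22 with spike-in scaling and 10 and 16 with planned normexp.

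SAUR genes rose in 24 of 27 cases, 20 of them at least 2-fold; 1 fell and 2 did not pass. The list median was 3.01, and the list was shifted upward (camera, adjusted p = 2.6e-08; adjusted p = 0.596 with an estimated correlation). SAUR19 (4.70 ± 0.38, adjusted p = 4.2e-05), SAUR9 (4.26 ± 0.15, adjusted p = 1.2e-06), SAUR65 (4.12 ± 0.43, adjusted p = 1.5e-04), SAUR20 (3.96 ± 0.45), SAUR23 (3.79 ± 0.30) and SAUR15 (3.46 ± 0.31) rose. SAUR68 (AT1G29490) showed 5.48 ± 0.40 (adjusted p = 2.6e-05) but was well above background on only 1 of the 4 wild-type arrays. Its signal lay at the floor of -9.97 on wild-type replicates 1 and 2, so the floor partly sets its change and SE. SAUR36 (-2.15 ± 0.08, adjusted p = 1.3e-06), linked to leaf senescence, fell. SAUR genes lie in tandem arrays of close copies whose probes may share signal, so the value of any single copy is uncertain. With the normexp background correction 16 SAUR genes rose, 1 fell and 2 of the members past the threshold turned sign. The rises of SAUR19 (2.305, adjusted p = 0.0508) and SAUR68 (0.077, adjusted p = 0.948) were no longer called. With normexp on the negative-control spots 24 rose and 1 fell.

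Of 17 brassinosteroid-related bHLH factors, 14 rose, 2 fell and 1 did not pass, and the list was shifted upward (median 0.95; camera, adjusted p = 0.0068; adjusted p = 0.706 with an estimated correlation). The PRE genes named here went both ways. PRE6 (3.47 ± 0.30, adjusted p = 5.6e-05), PRE5 (3.33 ± 0.20, adjusted p = 1.1e-05) and PRE1 (1.11 ± 0.35, adjusted p = 0.0273) rose, and PRE3 (-1.50 ± 0.23, adjusted p = 8.9e-04) fell. IBH1 (-1.47 ± 0.09, adjusted p = 1.4e-05), which inhibits cell elongation, fell as well. PRE1 was dim, its call was lost on leaving out any of 4 arrays (adjusted p up to 0.0703), and with normexp it turned to -1.33 (adjusted p = 0.201) while PRE5 lost its call (0.47, adjusted p = 0.587).

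Cell wall genes changed in both directions. Of 20 expansins, 9 rose, 3 fell and 8 did not pass (median 0.26, adjusted p = 0.245), with EXPA8 (2.88 ± 0.24, adjusted p = 5.2e-05) and EXPA11 (2.23 ± 0.23, adjusted p = 1.3e-04) upward and EXPA10 (-1.19 ± 0.09, adjusted p = 3.0e-05) downward. With normexp 7 expansins rose and 3 fell, and 3 of the members past the threshold turned sign. Of 24 xyloglucan endotransglucosylase/hydrolases, which remodel wall xyloglucan, 11 rose, 5 fell and 8 did not pass (median 0.28, adjusted p = 0.25). XTH19 (3.19 ± 0.12, adjusted p = 1.3e-06) and XTH8 (1.98 ± 0.10, adjusted p = 4.5e-06) rose, XTH24 (-1.38 ± 0.17, adjusted p = 3.3e-04) fell, and XTH22 (0.56 ± 0.19, adjusted p = 0.0352) rose with a call that was lost on leaving out any of 5 arrays (adjusted p up to 0.0788). With spike-in scaling 9 rose and 1 fell, and camera called the list upward with that scaling (median 0.16, adjusted p = 0.00944) and with normexp (median 0.17, adjusted p = 0.0284). Of 10 cellulose synthases, 8 rose, 1 fell and 1 did not pass (median 0.45, adjusted p = 0.061); CESA5 (1.11 ± 0.09) and CESA2 (0.75 ± 0.06) rose and CESA10 (-0.62 ± 0.06) fell. With spike-in scaling 2 cellulose synthases rose and 1 fell past the threshold, and with normexp 5 rose and 1 fell. Camera called the list upward with spike-in scaling (median 0.32, adjusted p = 0.0436), without the 3 marked arrays (median 0.57, adjusted p = 0.0313) and on leaving out either of 2 arrays (adjusted p = 0.0473 and 0.0435).

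**Figure D3:**
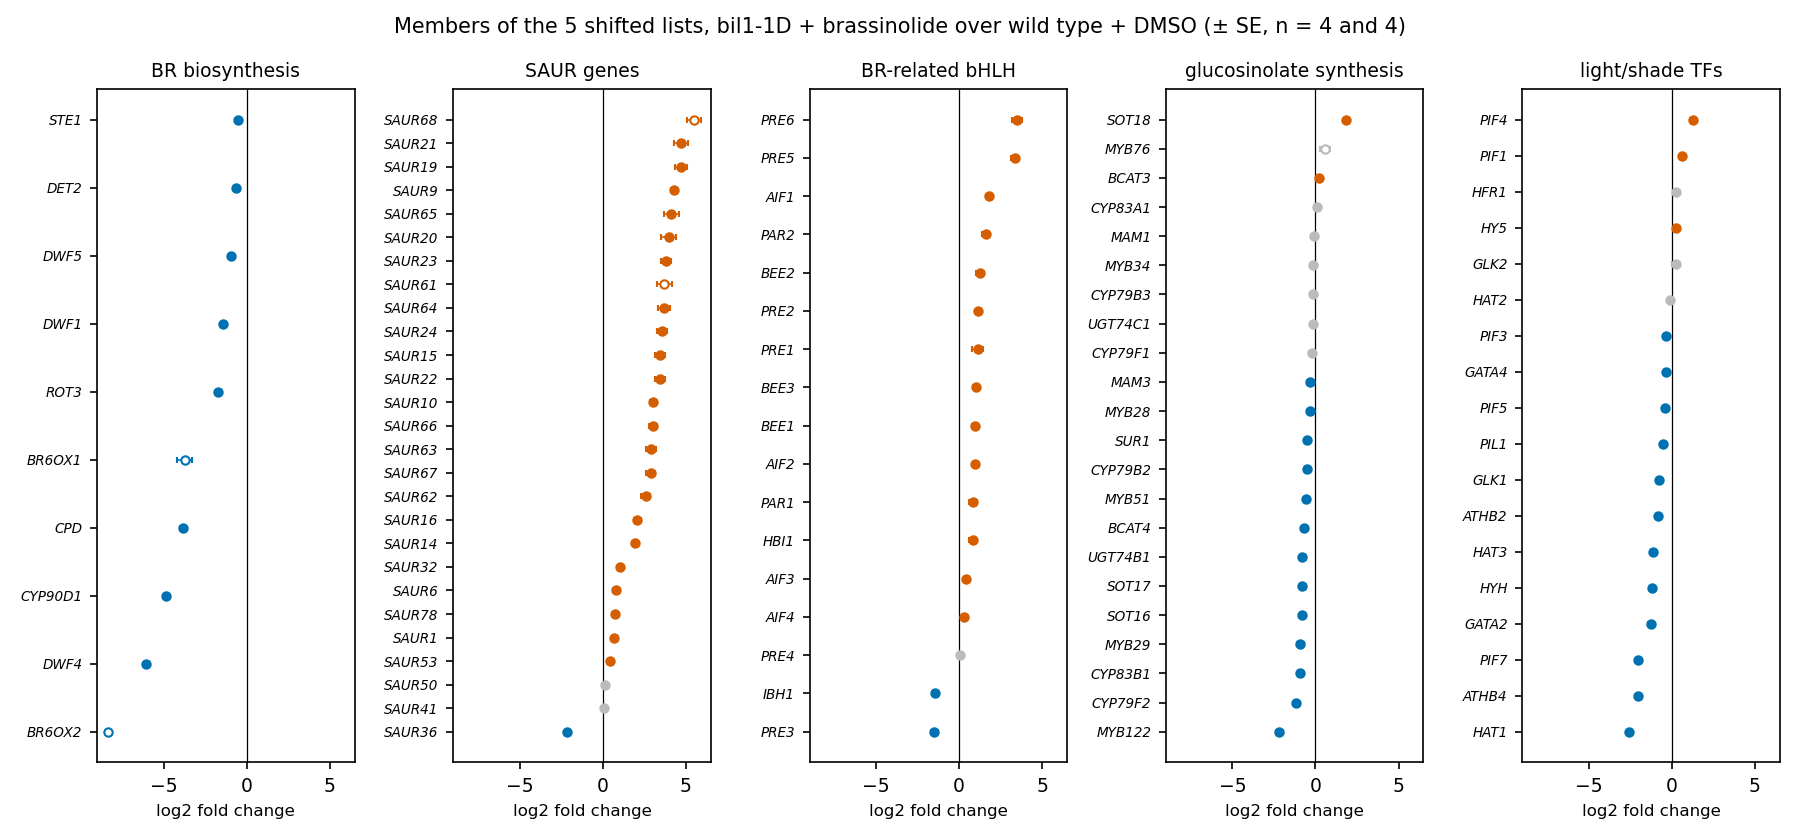
Log2 fold change ± SE (n = 4 and 4 arrays) of each member of the 5 lists called by camera, with orange for genes that rose, blue for genes that fell, grey for genes that did not pass and hollow points for genes not well above background on all arrays of a group. The changes run from -8.32 for BR6OX2, which is a fitted value and not the bound, to 5.48 for SAUR68, which the signal floor partly sets.

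Of 28 Aux/IAA genes, repressors of auxin response, 10 rose, 9 fell and 9 did not pass (median 0.06, adjusted p = 0.835). IAA6 (3.18 ± 0.38), IAA5 (2.95 ± 0.38) and IAA19 (1.46 ± 0.17) rose, and IAA31 (-1.58 ± 0.23, well above background on 3 of 4 mutant arrays) fell. With normexp 6 rose and 7 fell, and the calls of IAA6 (0.50, adjusted p = 0.615) and IAA5 (1.16, adjusted p = 0.145) were lost. Of 11 auxin conjugation and transport genes, 3 rose, 4 fell and 4 did not pass (median -0.41, adjusted p = 0.461). With normexp 1 rose and 5 fell, and 2 of the members past the threshold turned sign. The amido synthetase gene GH3.5 (-2.02 ± 0.15) and the efflux carrier gene PIN7 (-1.20 ± 0.20) fell; GH3.1 (1.92 ± 0.13) rose, but stood at -1.09 (adjusted p = 0.269) with normexp.

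Gibberellin genes rose in 13 of 23 cases, fell in 6 and did not pass in 4 (median 0.46, adjusted p = 0.197). This balance moved with the setting. With spike-in scaling 5 rose and 4 fell, and with negative-control normexp 14 rose and 4 fell. With planned normexp, whose fitted background was far below 0 on 3 wild-type arrays, 4 rose, 5 fell and 5 members past the threshold turned sign. The catabolic oxidase gene GA2OX8 (2.303 ± 0.09) rose and the biosynthetic oxidase gene GA20OX2 (-1.44 ± 0.22) fell. GA2OX1 rose (2.35 ± 0.50) and was well above background on 2 of the 4 wild-type arrays; with normexp it turned to -1.47 (adjusted p = 0.207) and the call of GA2OX8 was lost (0.24, adjusted p = 0.753). Of 10 ethylene biosynthesis genes, 2 rose, 6 fell and 2 did not pass (median -0.48, adjusted p = 0.255). ACS genes encode the enzyme that forms the ethylene precursor. ACS11 was not well above background on any mutant array (-9.35 ± 0.74 against -1.40 ± 0.32 in the wild type) and was at least 68.2-fold lower (adjusted p = 2.7e-06), and ACS7 (-2.86 ± 0.19, adjusted p = 1.5e-05) fell. ACS5 rose (5.32 ± 0.12, adjusted p = 1.3e-07; well above background on 3 of 4 wild-type arrays), but with normexp its call was lost (0.49, adjusted p = 0.638).

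Of 10 type-A response regulators, which respond to cytokinin, 1 rose, 3 fell and 6 did not pass (median -0.02, adjusted p = 0.53). ARR3 fell (-4.22 ± 0.50; well above background on 2 of 4 mutant arrays), ARR17 was at least 2.49-fold lower in the mutant (adjusted p = 0.00182; -7.64 ± 0.26 against -6.14 ± 0.54), and ARR5 (0.59 ± 0.13) rose. Normexp ended the calls of ARR17 (-2.21, adjusted p = 0.0563, and -0.20, adjusted p = 0.39, in the negative-control form, against a fitted -1.50 ± 0.26) and ARR5 (0.007, adjusted p = 0.985). Among 22 abscisic acid, cold and drought response genes, 7 rose, 7 fell and 8 did not pass (median -0.10, adjusted p = 0.781). With normexp 4 rose and 7 fell. The dehydrin genes ERD14 (1.34 ± 0.06, adjusted p = 3.2e-06) and COR47 (0.90 ± 0.08, adjusted p = 6.7e-05) rose, and RD29B fell (-3.38 ± 0.84, adjusted p = 0.00968) and was well above background on 1 of 4 mutant arrays. Its mutant signal ran from -5.49 on replicate 1 to -9.59 on replicate 3, so the size of its fall is uncertain.

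Of 21 jasmonate genes, 1 rose, 4 fell and 16 did not pass (median -0.16, adjusted p = 0.416). LOX2 (-1.12 ± 0.15, adjusted p = 4.2e-04) fell and JAZ12 (0.58 ± 0.08, adjusted p = 5.6e-04) rose. AOC3 (-0.82 ± 0.27, adjusted p = 0.0331) fell with a call that was lost on leaving out any of 6 arrays (adjusted p up to 0.0851) or with normexp (-0.79, adjusted p = 0.0543). Of 17 salicylate and immune genes, 2 rose, 6 fell and 9 did not pass (median -0.21, adjusted p = 0.525). The transcription factor gene WRKY40 (-2.28 ± 0.19, adjusted p = 4.7e-05) and PAD3 (-2.23 ± 0.24, adjusted p = 1.6e-04), the last enzyme of camalexin synthesis, fell, and WRKY18 (1.27 ± 0.10, adjusted p = 4.3e-05) rose.

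Of 22 glucosinolate synthesis genes, 13 fell, 2 rose and 7 did not pass (median -0.40; camera, adjusted p = 0.0083; adjusted p = 0.723 with an estimated correlation). MYB122 (-2.17 ± 0.21, adjusted p = 8.8e-05), a regulator of indolic glucosinolates, and CYP79F2 (-1.14 ± 0.15, adjusted p = 4.5e-04) fell. The sulfotransferase gene SOT18 (1.86 ± 0.12, adjusted p = 1.6e-05) rose. The list's call was lost with normexp (median -0.42, adjusted p = 0.185). Of 18 light and shade transcription factors, 12 fell, 3 rose and 3 did not pass (median -0.46; camera, adjusted p = 0.00773; adjusted p = 0.596 with an estimated correlation). HAT1 (-2.55 ± 0.16, adjusted p = 1.1e-05), ATHB4 (-2.02 ± 0.16, adjusted p = 4.5e-05) and GLK1 (-0.78 ± 0.09, adjusted p = 2.2e-04) fell and PIF4 (1.27 ± 0.17, adjusted p = 4.4e-04), a promoter of elongation growth, rose. GLK2, which with GLK1 controls chloroplast development, stood at 0.23 ± 0.21 (adjusted p = 0.389), and at -0.12 (adjusted p = 0.649) without the 3 marked arrays.

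Of 29 light harvesting, Rubisco small subunit and chlorophyll synthesis genes, 4 rose, 8 fell and 17 did not pass (median -0.09, adjusted p = 0.416). The balance turned to 8 rises and 5 falls with normexp and to 5 and 3 with median scaling, and was 0 and 3 with spike-in scaling, 1 and 8 with quantile normalization, 2 and 10 in the authors' value table, 2 and 7 with negative-control normexp and 0 and 9 without the 3 marked arrays, where camera called the list downward (median -0.19, adjusted p = 0.0207). HEMA1 (-0.62 ± 0.08, adjusted p = 3.0e-04) and LHCB1.1 (-0.46 ± 0.07, adjusted p = 8.9e-04) fell. RBCS2B (0.24 ± 0.08, adjusted p = 0.0278) rose, with a call that was lost on leaving out any of 6 arrays (adjusted p up to 0.0754) and under quantile normalization, the authors' value table and the mean of probes (adjusted p = 0.335, 0.191 and 0.217). Of 13 flavonoid genes, 1 rose, 5 fell and 7 did not pass (median -0.36, adjusted p = 0.155). CHI (AT3G55120; -1.63 ± 0.13) and PAP2 (AT1G66390; -2.51 ± 0.30, well above background on 2 of 4 mutant arrays) fell, and TT8 (0.60 ± 0.17) rose but turned to -0.86 (adjusted p = 0.125) with normexp, under which 9 flavonoid genes fell and 0 rose.

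Of 20 cell cycle genes, 7 rose, 4 fell and 9 did not pass (median 0.10, adjusted p = 0.57), with CYCD6;1 (0.69 ± 0.11) and CYCD3;1 (0.62 ± 0.09) upward and CYCD1;1 (-0.98 ± 0.18) downward; CYCD6;1 turned to -0.43 (adjusted p = 0.431) with normexp. The tally moved too, with 0 rises and 3 falls under spike-in scaling, where no member past the threshold turned sign. It was 2 rises and 5 falls with planned normexp and 7 rises and 4 falls with negative-control normexp. Of 15 circadian clock genes, 8 rose, 3 fell and 4 did not pass (median 0.28, adjusted p = 0.414). LHY (-1.19 ± 0.10, adjusted p = 4.9e-05), which peaks in the morning, fell, and PRR3 (0.59 ± 0.07, adjusted p = 2.7e-04) and ELF4 (0.53 ± 0.08, adjusted p = 8.5e-04) rose; with normexp 5 clock genes rose, 4 fell and the call of PRR3 was lost (0.16, adjusted p = 0.34), and with spike-in scaling no clock gene rose past the threshold and 3 fell. Of 6 flowering time genes, 2 rose, 3 fell and 1 did not pass (median -0.46, or -0.32 with AP1 at its bound; adjusted p = 0.604). FT (-0.90 ± 0.16) fell and AP1, not well above background on any mutant array, was at least 1.32-fold lower (-8.04 ± 0.15 against -7.09 ± 0.56, adjusted p = 0.0136); normexp ended its call (-2.09 against a fitted -0.94 ± 0.25, adjusted p = 0.0692) and the negative-control form turned it to 0.081 (adjusted p = 0.712). FLC (0.81 ± 0.25) rose, but its call was lost on leaving out any of 5 arrays (adjusted p up to 0.0685) and with the mean of probes (0.59, adjusted p = 0.0633), and it turned to -1.19 (adjusted p = 0.133) with normexp.

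Markers of other tissues were tested to show differences in seedling composition. Of 10 meristem and organ boundary markers, 5 rose, 3 fell and 2 did not pass (median 0.15, adjusted p = 0.841). STM (1.14 ± 0.24) and CUC1 (0.83 ± 0.14) rose, and LOF1 was at least 1.41-fold lower (-8.49 ± 0.57 against -7.00 ± 0.46, adjusted p = 0.00482; 0.056, adjusted p = 0.697, with negative-control normexp). Of 10 stomatal lineage markers, 3 rose, 2 fell and 5 did not pass (median 0.14, adjusted p = 0.781), with TMM (0.54 ± 0.08) and EPF1 (0.40 ± 0.08) upward and EPF2 (-0.91 ± 0.10) downward. Of 18 root markers, 5 rose, 6 fell and 7 did not pass; their median was 0.14 and their mean 0.03, while camera placed them downward (adjusted p = 0.781). PLT2 (-2.60 ± 0.15, well above background on 3 of 4 mutant arrays) and PLT1 (-1.03 ± 0.09) fell and the aquaporin gene TIP2;3 (1.204 ± 0.31) rose. Of 9 xylem and secondary wall markers, 3 rose, 3 fell and 3 did not pass; their median was -0.05 and their mean 0.02, and camera placed them downward (adjusted p = 0.841). PXY (0.58 ± 0.12) and MYB83 (0.39 ± 0.11) rose and ACL5 (-0.50 ± 0.16) fell. The call of ACL5 was lost on leaving out any of 3 arrays (adjusted p up to 0.0749) and that of MYB83 without the mutant's replicate 4 (adjusted p = 0.0508). With normexp, STM (-0.054, adjusted p = 0.91), CUC1 (-0.996, adjusted p = 0.126), EPF1 (-0.60, adjusted p = 0.174) and MYB83 (-1.44, adjusted p = 0.105) turned direction, and TIP2;3 lost its call (0.78, adjusted p = 0.106). The tallies shifted as well. With planned normexp, whose fitted background was far below 0 on 3 wild-type arrays, 0 meristem markers rose and 3 fell, as all 5 of the rises turned sign. Under it 1 stomatal marker rose and 3 fell, and 1 xylem marker rose and 2 fell. The negative-control form kept the balance near that of the main fit. There 6 meristem markers rose and 1 fell, 4 stomatal markers rose and 2 fell, and 3 xylem markers rose and 3 fell. With spike-in scaling 3 meristem markers rose and 2 fell, 0 stomatal markers rose and 2 fell, and 0 xylem markers rose and 1 fell. Root markers stood at 2 rises and 5 falls with normexp and without the 3 marked arrays, 3 and 4 with spike-in scaling, 7 and 6 with median scaling and 6 and 5 with negative-control normexp.

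Of 11 reference genes, often used as controls of RNA input, 4 rose, 2 fell and 5 did not pass (median 0.13, adjusted p = 0.416). ACT8 (0.46 ± 0.06) and TUB2 (0.41 ± 0.05) rose and CACS (-0.20 ± 0.04), a clathrin adaptor gene, fell. With spike-in scaling none of the 11 passed, but no member past the threshold turned sign. With planned normexp 7 rose and none fell, and with its negative-control form 4 rose and 1 fell. CACS lost its call with the mean of probes (-0.050, adjusted p = 0.344), and it turned to 0.27 (adjusted p = 0.0288) with normexp and to 0.13 (adjusted p = 0.114) with its negative-control form.

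Among genes well above background on all 8 arrays, the largest falls after DWF4 were those of AT5G57785 (-5.91 ± 0.13), AT2G03570 (-5.32 ± 0.12), RTFL1 (-4.91 ± 0.16), NSP2 (-4.85 ± 0.16) and CYP90D1, and all 6 of the largest rises were SAUR genes. Only 3 genes were well above background on every mutant array and on no wild-type array, against 446 the other way. The highest bounds of the former were those of AT3G25716, at least 5.46-fold higher in the mutant (-6.24 ± 0.08 against -9.10 ± 0.17, adjusted p = 6.1e-07), and AT4G16024, at least 5.25-fold higher (-6.28 ± 0.48 against -9.31 ± 0.48, adjusted p = 9.9e-05). With normexp these turned to -1.42 (adjusted p = 0.207) and -1.45 (adjusted p = 0.198). Of the 446, 45 had a bound over 2-fold and 223 a bound under 1, which gives no fold; the lowest signal called well above background was 11.3 to 15.6 on the wild-type arrays and 17.3 to 19.9 on the dimmer mutant arrays.

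**Figure D4:**
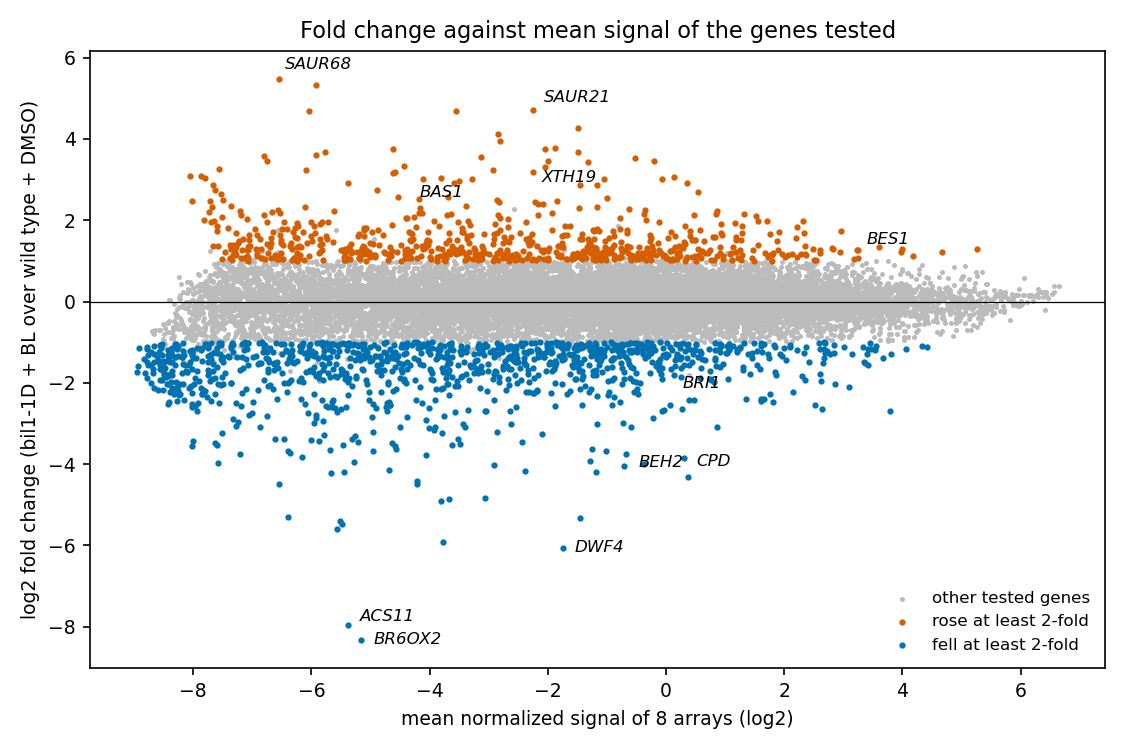
Log2 fold change of each of the 22101 tested genes against its mean normalized log2 signal over 8 arrays, with orange for genes that rose and blue for genes that fell at least 2-fold past the threshold, and grey for the others. Of the 1110 falls and 680 rises, 370 falls and 148 rises lie in the dimmest of 10 bins of equal gene number.

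Camera called 5 of the 29 lists (13 with spike-in scaling, which added the inactivation, signalling, brassinazole screen, expansin, xyloglucan, cellulose, gibberellin and flavonoid lists), and over all 458 tested members 161 rose and 142 fell. With an estimated correlation between genes, camera called 0 lists, with 1 at an unadjusted p under 0.05, while fry, which asks whether a list's genes move on balance one way, called 15 and placed the abscisic acid, meristem and xylem lists opposite to camera, none of them past its threshold. For each of the 5 lists, the mean of its members differed between the groups with the smallest p that the exact two-sided permutation test of 4 against 4 arrays can give (p = 0.0286), as it did for 11 of the 24 lists that camera did not call. The number of members past the threshold adjusted over the list alone equalled that over all genes for 23 lists. It was 17 against 16 for xyloglucan endotransglucosylase/hydrolases, 16 against 15 for light and shade transcription factors, 14 against 11 for the clock, 3 against 5 for jasmonate genes, 7 against 8 for salicylate genes and 3 against 12 for the light harvesting group.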

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

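The tests of the batch, of the background in dim spots and of the detection limit, and spike-in scaling, cyclic loess and negative-control normexp, were chosen only after the result was seen.

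The first pattern is the number of genes that changed, 12355 in all and 1790 at least 2-fold. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes on each count, the real one. The highest of the other splits called 0 genes by limma (2633 at an unadjusted p under 0.05, against 13573), so the difference follows the groups of arrays. Every other split mixes the slides, which puts the slide difference into its spread and leaves few calls possible. The test therefore cannot exclude a chance difference between cultures or slides. A smooth bias with brightness is argued against as the whole cause, since the median change of 10 bins by mean signal reached 0.12 in size and cyclic loess, which removes such a trend, kept 1681 of the 1790 changes at 2-fold. Background signal in dim spots stays open for the dimmest genes. In the dimmest bin 23.4% of the genes changed at least 2-fold, against 3.167% in the brightest, and the 2 dimmest bins held 572 of the 1110 falls and 277 of the 680 rises. Of these 849 changes, 256 turned sign with planned normexp and 142, all of them falls, with negative-control normexp, 398 in all. The former gave bin medians down to -1.88, with a fitted background far below 0 on 3 wild-type arrays, so its turns do not decide the question. The latter gave bin medians up to 0.33. Its fixed offset of 50 is a larger share of the dimmer slide's signal, which lifts dim genes there and favours turns of falls. Its turns therefore do not decide the question either, and it stays open. Slide and scan brightness stays open: 8 spike-in probes reading RNA added alike to every sample deviated from their median difference by up to 0.90 on the log2 scale (SE 0.15), near the bound of 1. Scaling to them kept 1626 of the 1790 changes at 2-fold and gave 1898. The main values were already divided by each array's own percentile, which takes out an even difference in brightness. The change of scaling moved the median by only -0.12, too little to undo most 2-fold changes whatever their cause. The kept changes therefore do not test even brightness as a cause of the 2-fold changes. All calls went from 12355 to 4399, with rises from 6679 to 1410 and falls from 5676 to 2989, while the median moved by -0.12. An even downward shift would add falls, and scaling to the spike-ins adds their spread between arrays to every gene. The lost calls therefore do not show that even brightness caused the smaller changes. Even brightness stays open for these and for the 2-fold changes. The batch of slide, labelling and hybridization cannot be told apart from the groups, with 0 slides holding both. Genotype and brassinolide also stay open and untested as biological causes, because they changed together.

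The number of shifted lists is less firm. Of the 35 splits, 23 gave at least 5 lists, with 10 at the highest of the others, so chance cannot be excluded for that number. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05, and fry called 15.

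The second pattern is that 446 genes were well above background in the wild type alone and 3 in the mutant alone. With 1 common limit for all arrays on the normalized scale, 53 genes were detected in the mutant alone and 135 in the wild type alone, and the wild-type share fell from 99.3% to 71.8%. A higher detection limit on the dimmer slide may therefore account for much of the imbalance, as the mean limit was -7.49 on the mutant arrays and -8.69 on the wild-type arrays. What remains was not explained, and a biological cause was not tested.

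In 13 of 282 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20, or 14.1. Values are normalized log2 signals. In the mutant these were the flavonoid list mean of replicate 3 (-3.03), ACS11 in replicate 2 (-8.24), AT5G57785 in replicate 4 (-6.32), BIL7 in replicate 4 (-3.45) and XTH24 in replicate 1 (3.43). In the wild type they were the brassinosteroid inactivation list mean of replicate 2 (-1.95), the cell cycle list mean of replicate 1 (-1.87), ACS7 in replicate 3 (0.70), FT in replicate 1 (-3.28), CACS in replicate 1 (2.44), XTH22 in replicate 3 (2.35), CYCD6;1 in replicate 1 (-4.52) and BEN1 in replicate 1 (-1.97). ACS11 was not well above background on any mutant array.

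Of 3474 tested probes that matched no locus, 1835 passed the threshold, 664 upward and 1171 downward, and 585 differed at least 2-fold.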

How the results depend on the processing

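The spike-in, cyclic loess, negative-control normexp and marked-array settings were chosen only after the result was seen. Of the 108 named genes past the threshold, 66 kept direction and call in every setting that tested them. Leaving out 1 array gave 10759 to 12358 genes, 1706 to 1893 genes at 2-fold, 5 to 6 lists and 470 to 572 genes detected in 1 group. Spike-in scaling gave 4399 genes and 13 lists, negative-control normexp 1164 genes at 2-fold, fry 15 lists and an estimated correlation 0 (1 at an unadjusted p under 0.05). In the other settings these totals stayed within 1.5 times, but not their parts: planned normexp gave 3973 rises and 5080 falls, 231 and 1902 at 2-fold, negative-control normexp 610 falls. The replicate number as a block gave 11344 genes, 1769 at 2-fold and 5 lists and ended the call of TT8. Same-numbered samples deviated with correlations of -0.28 to 0.17, and 3 of 8 samples correlated best with their own number. No pairing by number was detected, but so few arrays cannot exclude a weak one.

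The background mean fitted by normexp as planned was -934, -1158 and -599 on wild-type replicates 2 to 4 and 4.47 to 13.6 on the other arrays, while negative-control spots averaged 17.2 to 26.1 over all arrays. Under it 14 named genes lost their call and 13 turned: MYB83 -1.44, EPF1 -0.60, TT8 -0.86, CYCD6;1 -0.43, FLC -1.19, CUC1 -0.996, PRE1 -1.33, STM -0.054, GH3.1 -1.09, GA2OX1 -1.47, AT3G25716 -1.42, AT4G16024 -1.45 and CACS 0.27. Lists whose camera direction turned had medians of -0.10 (salicylate), 0.11 (light harvesting), -0.16 (cell cycle), -0.96 (meristem), -0.29 (stomatal) and 0.038 (root), the glucosinolate call ended, and the xyloglucan endotransglucosylase/hydrolase and reference lists were newly called. Negative-control normexp turned LOF1 to 0.056, AP1 to 0.081 and CACS to 0.13; its fixed offset is a larger share of the dimmer slide's signal. Without the marked arrays GLK2 stood at -0.12.

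Lists far from any call also turned direction, and the cause was not tested: Aux/IAA with no filter (median 0.056), abscisic acid without the marked arrays (-0.093) and with fry (-0.10), meristem with median scaling (0.21) and fry (0.15), root with spike-in scaling (0.013), and xylem with quantile normalization (0.048), the authors' table (0.046), the mean of probes (-0.052), fry (-0.052), negative-control normexp (0.15) and cyclic loess (0.046). Blocks for slide and scan were not run, since each holds 1 group.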

Other observations

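The families below and the permutation test of the clock genes were chosen only after the result was seen; the test of morning against evening genes was set before.

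Gene families defined by symbol, some with members in the lists above, also moved. A family here is the letter prefix of the gene symbol, with at least 8 tested genes, and 224 families were tested in each direction by Fisher's exact test against all tested genes, 448 tests in all, of which 15 passed after Benjamini-Hochberg adjustment; 6 families are described here. Of the others, SAUR and XTH held in each setting, while BGLU ended in 15 settings, EXPA in 11, MYB in 8, RTFL in 6, LCR in 3, ACS in 2 and IAA in 1. Fisher's test counts the members of a family as independent genes. Close copies may move together or share probe signal, as said for SAUR genes, so the adjusted p-values of families may be too small. Arabinogalactan protein genes, which encode cell surface proteoglycans, rose at least 2-fold in 8 of 28 cases (adjusted p = 2.1e-04), among them AGP41 (2.06 ± 0.15), AGP21 (1.97 ± 0.09) and AGP7 (1.73 ± 0.13), and 0 fell as much. Cysteine-rich receptor-like kinase genes rose in 8 of 38 cases and fell in 1 (adjusted p = 0.00149), led by CRK20 (2.33 ± 0.19) and CRK16 (1.98 ± 0.11). Over all settings run, 7 to 11 AGP genes and 5 to 12 CRK genes rose at least 2-fold.

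UDP-glycosyltransferase genes, whose enzymes attach sugars to hormones and metabolites, fell at least 2-fold in 13 of 54 cases (adjusted p = 2.2e-04), among them UGT73B4 (-4.19 ± 0.18) and UGT73B5 (-2.55 ± 0.13), and 0 rose as much. Symbols starting with CYP, mostly cytochrome P450 genes, fell in 31 of 186 cases and rose in 8 (adjusted p = 8.5e-07; 28 of the 177 outside the lists fell), with CYP78A6 (-3.63 ± 0.23) and CYP710A1 (-2.80 ± 0.28) among the falls. Of the 31, 8 were not well above background on any mutant array and have only bounds, which lie under 2-fold for CYP705A23 (1.07), CYP71B16 (1.15), CYP94B2 (1.42) and CYP71A20 (1.83); among genes well above background on all arrays, 21 of 167 fell (adjusted p = 1.4e-04). Genes with the nitrate transporter prefix NRT fell in 5 of 12 cases (adjusted p = 0.0119), led by NRT1.8 (-2.64 ± 0.29), and ABCC transporter genes in 5 of 15 (adjusted p = 0.0243), led by ABCC15 (-2.58 ± 0.12). Over all settings run, 11 to 17 UGT, 17 to 47 CYP, 3 to 6 NRT and 5 ABCC genes fell at least 2-fold. The calls of AGP, CRK, UGT and CYP held in each setting, while that of NRT ended in 13 settings (adjusted p up to 0.371) and that of ABCC with normexp (adjusted p = 0.152).

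The third pattern is that clock genes differed by phase. Morning genes (CCA1, LHY, RVE1, RVE8 and PRR9) had a median change of -0.65, with 3 falling and 1 rising, and 8 evening genes a median of 0.32, with 5 rising and 0 falling by limma. The difference of -0.97 (-1.004 to -0.776 leaving out 1 gene, -1.83 to -0.55 over all settings run) is what a harvest at different times of day would give, which may be a candidate explanation. Chance between arrays is argued against by the exact permutation p of 0.0286, the smallest the design allows. That p does not set the clock genes apart, since the groups did not overlap for 52.2% of all tested genes. An effect of genotype or of brassinolide on the clock stays open and untested, as does the slide.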
